A study of Mus musculus with 6 samples.

How the data were processed

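Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in 6 libraries from mouse intestinal epithelial cultures. The 3 groups held 2 libraries each: wild-type organoids (WT), tumoroids lacking Apc (A), and tumoroids lacking Apc, Smad4 and Trp53 with the KrasG12D allele (AKSP). Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

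The authors deposited a table of raw counts for 166913 peaks, with whole numbers that sum to a different total in each library. A second deposited table holds a normalised signal. Its values equal the counts divided by 1 size factor per library, as checked on the file. It was used only to obtain the authors' size factors. These factors were 1.18 to 1.19 times those of the median-ratio method recomputed here on all peaks. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trim Galore 0.6.6, Bowtie2 2.1.0, Picard 2.2.4, SAMtools 1.11, bedtools 2.29.2 and DESeq2 1.30.1, on the mouse build mm10 (GRCm38). The peak caller, any shift of reads for the Tn5 cut and whether reads or fragments were counted are not given in the sources used here. Whether peaks were called per library or on pooled libraries is likewise not given, and this affects which weak peaks enter the table. Peak coordinates are printed as the authors' file gives them, and whether they count from 0 or 1 is not stated.

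Total counts in peaks ranged from 34962644 to 129236982 per library, a 3.70-fold range. The median count per peak lay between 42 and 183. No depth of all mapped reads was given in the files, so the share of reads in peaks is not known.

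Peaks and genes were paired through a RefSeq gene table of the same build (GRCm38.p6). This table gives the start and end of each gene and no strand, so transcription start sites could not be told from gene ends. Each peak was therefore assigned to the protein-coding gene with the nearest end, of either kind, within 50 kb, in place of the planned nearest start site. Peaks within 1 kb of either end of a gene are called gene-end peaks, and they replace the planned promoter class. In all, 131017 peaks (78.5%) were assigned, to 18692 of 21887 protein-coding genes, and 22010 peaks (13.2%) were gene-end peaks. A gene locus is the sum of the counts of all peaks assigned to a gene. A peak may act on another gene than the nearest, and accessibility of a locus is not expression.

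Peaks and gene loci were tested with edgeR 4.0.16 on the deposited counts in R 4.3.3. Features passed filterByExpr (166903 peaks and 18691 loci), libraries were scaled with TMM, and the quasi-likelihood F test was applied to 1 fit of all 6 libraries with group means as the model. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as a call. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values are TMM-scaled, and their SDs are between the 2 libraries of a group. Where all libraries of a group held 0 counts, folds are lower bounds against 3 counts over the group.

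Before the data were examined, 19 gene lists were fixed: Wnt pathway targets, intestinal stem cell markers, fetal and regenerative epithelium markers, YAP/TEAD targets, enterocyte markers, goblet cell markers, Paneth cell markers, enteroendocrine markers, tuft cell markers, TGF-beta and BMP targets, p53 targets, MAPK and AP-1 targets, intestinal identity transcription factors, gastric and squamous epithelium markers, genes of EMT and matrix remodelling, stromal, immune and endothelial markers, colon and posterior gut markers, proximal small intestine markers, and housekeeping genes. Of their 349 different genes, 348 were in the annotation. Members are counted only where a gene had a tested locus, which held for 7 of the 14 listed Paneth genes. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 19 lists of a comparison. The rule for named loci was also fixed then. It takes the 6 largest rises and 6 largest falls per comparison among called loci with mean CPM at or above the median and groups that do not overlap. It adds up to 3 members of each list with the smallest p, the 4 targeted genes, and the 3 peaks with the largest rise and fall by the same criteria. This rule names about 70 loci per comparison. Some lists are given by their counts with few or no members written out, and the choice of those lists was made after the values were seen.

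The scripts were tested on simulated data drawn from the libraries' means, depths and trended dispersions, so spread particular to single peaks was left out. Far fewer features were changed than were called in the data, and none of them had the lowest mean counts. Among simulated peaks changed 4-fold, the test recovered 95.3% for A vs WT, 98.6% for AKSP vs WT and 97.7% for AKSP vs A, over 166896 peaks. At a change of 2-fold it recovered 34.9%, 30.0% and 48.1%. Among simulated loci changed 1.5-fold, it recovered 92.1%, 88.7% and 92.5%, over 18690 loci. Under these settings, false calls made up 3.19% to 7.14% of calls. With the Wnt list alone shifted in A, camera called it and 1 other list in A vs WT.

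The overlap of the comparisons with WT was set beside 10 simulations of unchanged groups, since both use the same WT libraries. Alternatives covered scaling (DESeq2 size factors, the authors' factors, library sizes alone, abundance-trended offsets), the DESeq2 1.42.0 Wald test, filters, a test against a 1.5-fold change, the samples fitted, a replicate block, distances of 10 kb and 100 kb, gene-end peaks alone, each library left out, equal depth by thinning, and removal of each chromosome's median. Their effects are given in the closing section. No reference genome was used, so the planned motif tests and GC corrections were not run. The replicate numbers shared by the labels were not used as pairs.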

Results

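ATAC-seq peak counts were compared between wild-type mouse intestinal organoids (WT), Apc-deficient tumoroids (A) and tumoroids that also carried KrasG12D and lacked Smad4 and Trp53 (AKSP). Organoids are cultures of primary epithelium grown in a gel, and tumoroids are such cultures with tumour-associated alleles. Apc restrains Wnt signalling, and the 4 alleles together model later steps of colorectal cancer. Each group had 2 libraries. Counts in peaks summed to 39329657 and 34962644 in the WT libraries, 129236982 and 39185039 in A, and 88834369 and 55410659 in AKSP.

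Libraries grouped by genotype. Across peaks, which are not independent replicates, log2 CPM correlated at r = 0.964 between the WT replicates, 0.977 in A and 0.973 in AKSP. Between groups, r was 0.868 to 0.879 for WT and A, 0.906 to 0.924 for A and AKSP, and 0.768 to 0.782 for WT and AKSP. The leading principal component held 71.5% of the variance and the next 14.4%. Peaks that differed over 4-fold between replicates numbered 1365 in WT, 312 in A and 77 in AKSP.

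The targeted genes were examined to check the labels. No peak in Apc, Kras, Smad4 or Trp53 fell to 0 counts in any tumoroid group. In Apc (chromosome 18, 34220297 to 34322190), no peak lay beyond 34287724, so the rest of the gene was not measured. The Apc locus did not pass the test in A (log2 fold change -0.05 ± 0.08 SE), and it fell in AKSP against WT (-0.38 ± 0.08), where it did not pass the test with peaks within 10 kb (-0.17) or gene-end peaks only (-0.13). One peak inside Apc, at 34247148 to 34247901, had log2 fold changes of -2.94 ± 0.27 in A and -3.26 ± 0.28 in AKSP (edgeR adjusted p = 1.40e-08 and 9.63e-10). The Smad4 locus (chromosome 18, 73634790 to 73703791) fell in A by 0.26 and in AKSP by 0.57 on the log2 scale. Within Smad4, the peak at 73665353 to 73666829 had a log2 fold change of -1.80 ± 0.19 in AKSP against WT (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.92e-08) and -0.41 ± 0.18 in A (0.0859). The Smad4 peak at 73676399 to 73676791 was low in A, where Smad4 is not targeted, and in AKSP (-1.94 ± 0.30 and -2.17 ± 0.31). The peak at 73660200 to 73660626 was at -1.08 ± 0.33 and -2.37 ± 0.35. These 4 peaks were chosen after their values were seen. The Kras locus (chromosome 6, 145216699 to 145250420) fell by 0.40 in A and by 0.93 in AKSP. With gene-end peaks only, Kras (0.05 in A, -0.15 in AKSP) and, in A, Smad4 (-0.03) did not pass the test, nor did Kras (-0.22) and Smad4 (-0.14) in A with peaks within 10 kb. Smad4 in AKSP passed it at -0.33 within 10 kb, -0.29 with gene-end peaks only and -0.37 with chromosome medians removed. Smad4 in A also lost its call without WT replicate 1 (-0.25), WT replicate 2 (-0.27) or A replicate 1 (-0.25). The Trp53 locus (5 peaks) did not pass the test in any comparison, at 6.01 ± 4.2 CPM in WT, 6.30 ± 0.15 in A and 5.39 ± 0.46 in AKSP (mean ± SD, n = 2). In AKSP against WT it passed the test in opposite directions when 1 WT library was left out, at 0.83 without WT replicate 2 and -0.74 without WT replicate 1 (edgeR adjusted p = 0.0228 and 0.0185). In A it was at 1.06 without WT replicate 2 (0.0141). This sum leaves out the strong peak over one end of Trp53 (69577657 to 69582132, 53.9 ± 1.3 CPM in WT), whose log2 fold change was 0.36 ± 0.15 in A and 0.43 ± 0.15 in AKSP (edgeR adjusted p = 0.0748 and 0.0214). Summed over the peaks within 50 kb that had its gene body as the nearest, Trp53 rose by 0.40 in A and 0.50 in AKSP (0.00149 and 0.000149). With gene-end peaks only it was at 1.56 and 1.26 (0.00650 and 0.0145). The positions of the deletions are not given in the sources used here, so these peaks do not check the labels. The medians of all peaks on chromosomes 18 and 6 were -0.17 and -0.20 in AKSP vs A. With chromosome medians removed, Apc and Smad4 no longer differed between AKSP and A (log2 fold changes -0.16 and -0.14). The fall of Apc in AKSP against WT did not pass the test there either (-0.18).

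The comparison of A with WT asked what accompanies loss of Apc. Xist and Y-linked peaks also separated WT from both tumoroid groups, as a difference in sex would, so sex-linked signal differed along with genotype. This limit holds for every comparison with WT, as set out under Other observations. Of the listed loci, 12 of 22 fetal and regenerative markers and 8 of 18 gastric and squamous markers rose, and 19 of 25 enterocyte markers fell. The calls of these lists by limma camera did not hold with an estimated correlation (adjusted p = 0.660). Tacstd2 (chromosome 6, 67534059 to 67535822), which encodes the fetal epithelial surface protein Trop2, rose 8.01-fold, from 14.6 ± 0.79 CPM in WT to 117 ± 2.5 in A (SD, n = 2). Msln (chromosome 17, 25748613 to 25754378), encoding mesothelin, rose 7.89-fold, from 7.97 ± 0.062 to 62.8 ± 3.1 CPM. Fabp1 (chromosome 6, 71199879 to 71205034), encoding the enterocyte fatty acid-binding protein, fell to 0.202 of WT, from 18.9 ± 0.78 to 3.85 ± 0.39 CPM.

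Of 18691 loci, 3741 were higher and 3965 lower in A. Among peaks, 27898 were higher and 29128 lower, or 34.2% of those tested. Of the called peaks 48.9% were higher, or 56.9% with library sizes alone and 53.4% with abundance-trended offsets. The other loci with the largest rises were Abca12, a lipid transporter of keratinocytes (log2 fold change 2.72 ± 0.12 SE), Spef2 (2.61 ± 0.13), the trypsin gene Prss2 (2.49 ± 0.15) and Sema3e, a semaphorin (2.40 ± 0.12). The largest falls were at Lmcd1 (-3.26 ± 0.13), Epb41l3 (-3.04 ± 0.10), 1700037H04Rik (-2.41 ± 0.20), the receptor phosphatase gene Ptprm (-2.39 ± 0.12), the lipid phosphatase gene Plpp3 (-2.09 ± 0.08) and Unc93a (-2.05 ± 0.12). At these 12 loci the adjusted p from edgeR lay between 1.44e-08 and 3.21e-06. The rule took only called loci at which both A libraries lay beyond both WT libraries.

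Wnt targets moved with loss of Apc: 13 of 25 rose and 3 fell, with the counts adjusted over the list alone also 13 and 3. Apcdd1, a Wnt inhibitor gene, rose by 1.37 ± 0.09 (log2, SE), Tnfrsf19 by 1.48 ± 0.09 and Prox1 by 1.21 ± 0.10. Camera called the list (limma, adjusted p = 0.0130; adjusted p = 0.660 with an estimated correlation). Stem cell markers split, with 8 of 18 higher and 4 lower (8 and 6 adjusted over the list alone; limma camera adjusted p = 0.440). Axin2, the negative-feedback gene of the pathway, rose by 0.79 ± 0.07, while Olfm4, a marker of crypt stem cells, fell by 1.92 on the log2 scale, from 68.2 ± 11 to 17.9 ± 3.6 CPM.

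Fetal and regenerative markers rose at 12 of 22 loci and fell at 2 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0108, limma; adjusted p = 0.660 with an estimated correlation). Besides Tacstd2 and Msln, Anxa1 rose by 1.49 ± 0.11. Gastric and squamous markers rose at 8 of 18 and fell at 1 (the same counts adjusted over the list alone), led by the stomach claudin gene Cldn18 (2.02 ± 0.10) and the keratin genes Krt4 (1.86 ± 0.17) and Krt13 (1.05 ± 0.12). Camera called them at adjusted p = 0.0256 (limma; adjusted p = 0.660 with an estimated correlation). YAP/TEAD targets gave no call as a list, with 7 of 23 higher and 4 lower (8 and 6 adjusted over the list alone; limma camera adjusted p = 0.582). The smallest p-values among them were at Ankrd1 (2.32 ± 0.11), Igfbp3 (1.67 ± 0.11) and Ccdc80 (1.22 ± 0.12). With peaks within 100 kb, Ankrd1 was at 1.03. The list's median was -0.05 and its mean 0.21.

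Enterocyte markers fell at 19 of 25 loci and rose at none (20 and 0 adjusted over the list alone; limma camera adjusted p = 3.76e-06; adjusted p = 0.660 with an estimated correlation). Apoc3, an apolipoprotein gene, fell to 0.217 of WT and Mttp, the lipoprotein-assembly gene, to 0.259. Targets of p53 rose at 12 of 23 loci and fell at 1 (13 and 3 adjusted over the list alone; limma camera adjusted p = 0.0256; adjusted p = 0.660 with an estimated correlation). Mdm2, which restrains p53, rose by 0.55 ± 0.08, and the repair genes Polk and Xpc rose by 0.47 ± 0.08 and 0.53 ± 0.09.

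Secretory lineages gave no list call in the planned test. The enteroendocrine list was called lower with gene-end peaks only (limma camera adjusted p = 0.0243) and without A replicate 1 (0.0328), and the goblet list higher with peaks within 10 kb (0.0435). Goblet markers rose at 4 of 14 and fell at 2 (limma camera adjusted p = 0.377). Paneth markers rose at 2 of the 7 with a tested locus (14 were listed) and fell at 1 (0.905). Among Paneth markers, Mmp7 rose by 1.64 ± 0.16, while lysozyme (Lyz1) fell by 1.51. Enteroendocrine markers rose at 2 of 22 and fell at 9 (0.109), with Pax6 down by 0.83 and Rfx6 by 1.46, and Scg2 up by 1.27. Tuft markers rose at 4 of 22 and fell at 5 (0.907), with Ptgs1 (0.98 ± 0.09) and the cytokine gene Il25 (1.69 ± 0.17) higher and Alox5ap lower (-0.92 ± 0.15). The tuft median was 0.01 and its mean 0.02, while the camera direction was down. The counts of these 4 lists were 5 and 3, 2 and 2, 2 and 9, and 5 and 6 adjusted over the list alone. Itln1, a Paneth marker at 0.44 ± 0.15, did not pass the test without WT replicate 2 (0.32), A replicate 1 (0.42) or A replicate 2 (0.46) and was at -0.65 with gene-end peaks only.

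Of the remaining lists, colon and posterior gut markers rose at 1 of 10 and fell at 4 (limma camera adjusted p = 0.0547; 0.0103 without A replicate 1 and 0.0475 with chromosome medians removed), and proximal small intestine markers rose at 1 of 7 and fell at 3 (0.191). Pdx1, a regulator of the proximal gut, fell by 0.77, the lactase gene Lct by 1.49 and Cybrd1 by 0.67 on the log2 scale (Cybrd1 was at -0.65, without a call, when A replicate 1 was left out). EMT and matrix genes rose at 3 of 18 and fell at 8 (0.215). Intestinal identity factors rose at 3 of 20 and fell at 5 (0.547), TGF-beta and BMP targets at 5 and 6 of 19 (0.767), and MAPK and AP-1 targets at 8 and 4 of 23 (0.440). Adjusted over the list alone, these counts were 1 and 4, 1 and 3, 3 and 9, 3 and 5, 5 and 6, and 9 and 4. Markers of stromal, immune and endothelial cells rose at 4 of 22 and fell at 6 (0.740), among them Pdgfra (-0.59 ± 0.08) and Acta2 (-0.52 ± 0.09), with Sox10 higher (0.75 ± 0.13). Housekeeping loci rose at 5 of 13 and fell at none (0.170), with Rpl13a at 0.73 ± 0.09, Ppia at 0.59 ± 0.10 and Eef2 at 0.58 ± 0.09. For these lists, the counts adjusted over the list alone were 4 and 6, and 5 and 0.

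At single peaks, the largest rises in A were on chromosome Y. The Ddx3y peak (1285723 to 1286817) had 0 counts in both WT libraries and 12.8 ± 0.092 CPM in A, at least 307-fold higher. Peaks nearest Gm21379 (12668576 to 12669514) and Rbm31y (17381208 to 17382122) were at least 241-fold and 231-fold higher. The largest falls were at peaks outside protein-coding genes on chromosome 12 (113747986 to 113748461, log2 fold change -6.77 ± 0.45), chromosome 4 (51808676 to 51809039, -6.65 ± 0.37) and chromosome 14 (89607571 to 89607970, -6.64 ± 0.30). Other kinds of gene were not checked there. The peak on chromosome 12 differed between the WT libraries, at 16.8 and 6.54 CPM. With peaks within 10 kb only, Fabp1 (-0.34), Alox5ap (-0.06), Scg2 (0.47), Sox10 (0.34) and Acta2 (-0.37) did not pass the test. With gene-end peaks only, neither Spef2 (-0.31) nor Ccdc80 (0.40) did. Plpp3 passed the test with smaller falls, at -0.85 within 10 kb and -0.69 with gene-end peaks only, and smaller rises remained past it at Prss2 within 10 kb (1.58) and at Sema3e (1.52) and Apcdd1 (0.33) with gene-end peaks only. Also past the test were Apcdd1 (0.89) and Olfm4 (-2.88) within 10 kb and, with gene-end peaks only, Polk (0.24). Gene-end peaks only gave larger values at Axin2 (1.91), Prox1 (1.88), Mmp7 (2.87), Ptgs1 (1.54), Cybrd1 (-2.83), Olfm4 (-2.91), Pdgfra (-1.05) and Pdx1 (-1.16). The call of the p53 list was lost without A replicate 2 (limma camera adjusted p = 0.166), and that of the gastric and squamous list without A replicate 1 (0.123) or with peaks within 10 kb (0.0599).

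The comparison of AKSP with WT covered all 4 alleles, and sex-linked signal differed along with them, as for A. In AKSP, 17 of 22 fetal and regenerative markers and 9 of 18 gastric and squamous markers rose, and 20 of 25 enterocyte markers fell. The limma camera calls of these lists did not hold with an estimated correlation (adjusted p = 0.799). Msln rose 16.3-fold, from 7.97 ± 0.062 CPM in WT to 130 ± 27 in AKSP (SD, n = 2). Igfbp3 (chromosome 11, 7206086 to 7215498), encoding an insulin-like growth factor-binding protein, rose 10.2-fold to 115 ± 0.69 CPM. Lmcd1 (chromosome 6, 112273758 to 112330423) fell to 0.0426 of WT, from 93.1 ± 8.1 to 3.94 ± 0.39 CPM.

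In AKSP, 5790 loci were higher and 5665 lower than in WT, and 41418 peaks were higher and 42621 lower, or 50.4% of those tested. The share of called loci that were higher was 50.5%, or 43.1% with library sizes alone. Prss2 (3.40 ± 0.15 log2, SE), Armc3 (3.16 ± 0.10), Sema3e (3.03 ± 0.12) and Cldn18 (2.98 ± 0.10) completed the largest rises. The largest falls after Lmcd1 were at Epb41l3 (-4.10 ± 0.11), Plpp3 (-3.45 ± 0.09), Gm826 (-3.20 ± 0.21), Morc1 (-3.15 ± 0.17) and the manganese transporter gene Slc30a10 (-3.05 ± 0.11). At the 12 loci the edgeR adjusted p lay between 3.59e-10 and 7.95e-08.

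Fetal and regenerative markers rose at 17 of 22 loci and fell at 1 (the same counts adjusted over the list alone; limma camera adjusted p = 0.000253; adjusted p = 0.799 with an estimated correlation). Tacstd2 rose by 2.49 ± 0.12 and Anxa1 by 2.36 ± 0.11. Gastric and squamous markers rose at 9 of 18 and fell at 1 (9 and 1 adjusted over the list alone; limma camera adjusted p = 0.0267; adjusted p = 0.799 with an estimated correlation). Among them Krt13 rose by 2.17 ± 0.12 and Tff1, a trefoil peptide of the stomach, by 2.70 ± 0.16. Enterocyte markers fell at 20 of 25 and rose at 1 (21 and 1 adjusted over the list alone; limma camera adjusted p = 0.000253; adjusted p = 0.799 with an estimated correlation). Cyp3a11, a cytochrome P450 gene, fell by 2.78, Fabp1 by 2.80 and the peptidase gene Dpp4 by 2.06 on the log2 scale.

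Wnt targets split in AKSP, with 14 of 25 higher and 8 lower (limma camera adjusted p = 0.255). Cd44 (1.27 ± 0.07), Tnfrsf19 (1.63 ± 0.10) and Apcdd1 (1.16 ± 0.09) rose. Stem cell markers rose at 10 of 18 and fell at 6 (0.525), with Aqp4 at -2.63 ± 0.11 and Olfm4 at -2.83 ± 0.16. Their median was 0.25 and their mean -0.18. YAP/TEAD targets rose at 11 of 23 and fell at 8 (0.370), with Ankrd1 at 3.13 ± 0.11 (1.75 with peaks within 100 kb) and Myof at 1.74 ± 0.07. MAPK and AP-1 targets rose at 12 of 23 and fell at 2 (0.126, or 0.0362 and called with peaks within 100 kb), led by Ier3 (2.18 ± 0.09), Fosl1 (0.87 ± 0.08) and Junb (0.55 ± 0.08). Adjusted over the list alone, the counts of these 4 lists were the same.

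Targets of p53 rose at 7 of 23 loci and fell at 8 (limma camera adjusted p = 0.899; 7 and 8 adjusted over the list alone), with Polk and Xpc higher (0.91 ± 0.08 and 0.78 ± 0.09) and Pmaip1 lower (-0.65 ± 0.08, or -0.21 and not past the test with gene-end peaks only). The p53 median was -0.08 and the mean -0.02, while the camera direction was up. TGF-beta and BMP targets rose at 8 of 19 and fell at 5 (0.825; 9 and 5 adjusted over the list alone), with a median of 0.17 and a mean of -0.11. Serpine1 rose by 1.85 ± 0.12, while Msx1 fell by 1.88 and Tgfbi by 1.81. Lysozyme (Lyz1) fell by 3.17 and Mptx1 by 1.91, and Mmp7 rose by 1.43 ± 0.16 among Paneth markers, of which 2 of 7 rose and 3 fell (0.525). Goblet markers rose at 5 of 14 and fell at 5 (0.899), with the mucin gene Muc2 at 1.46 ± 0.15, Spdef at 1.17 ± 0.17 and Tff3 at 1.04 ± 0.11. These 2 lists had the same counts adjusted over the list alone.

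Posterior gut markers fell at 6 of 10 and rose at 1 (limma camera adjusted p = 0.146), among them Retnlb (-2.996 ± 0.28), Aqp8 (-1.04 ± 0.10) and Slc37a2 (-0.90 ± 0.12). Pdx1 rose by 0.75 ± 0.08. Identity factors rose at 5 of 20 and fell at 7 (0.899), with Cdx2 at 0.69 ± 0.07, Vdr at -1.26 ± 0.07 and Hnf4g at -0.66 ± 0.08. Stromal, immune and endothelial markers rose at 3 of 22 and fell at 9 (0.396), with Pdgfra at -0.68 ± 0.08, Sox10 at 0.92 ± 0.13 and Tek at 0.54 ± 0.08. Housekeeping loci rose at 7 of 13 and fell at none (0.126), including Ppia, Actb and Polr2a (0.69 ± 0.10, 0.50 ± 0.07 and 0.50 ± 0.08). Adjusted over the list alone, these 4 lists gave 1 and 6, 5 and 7, 4 and 10, and 7 and 0. Enteroendocrine markers rose at 3 of 22 and fell at 10 (0.169), tuft markers at 6 and 7 of 22 (0.397), EMT and matrix genes at 6 and 8 of 18 (0.518) and proximal markers at 1 and 3 of 7 (0.525), with the same counts adjusted over the list alone. With peaks within 10 kb only, Pdgfra (-0.19) did not pass the test.

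At single peaks, a Cpeb4 peak inside the gene (chromosome 11, 31922572 to 31922907) had 0 counts in WT and 2.99 ± 0.43 CPM in AKSP, at least 71.9-fold higher. The Ddx3y and Gm21379 peaks on Y were at least 90.9-fold and 67.0-fold higher. Peaks near Mettl17 (chromosome 14, 51877423 to 51878072) and Calr4 (chromosome 4, 109212052 to 109212644) had 0 counts in AKSP, at least 233-fold and 98.0-fold lower than in WT. The peak on chromosome 14 named for A was also low here (-6.87 ± 0.31). With gene-end peaks alone, Muc2 was at -0.53 and Hnf4g at -0.01, so their values rest on peaks farther from the gene ends. Past the test but smaller were Prss2 (1.71), Fabp1 (-1.36), Apcdd1 (0.56) and Polk (0.58) within 10 kb. So were Tnfrsf19 (0.74), Cd44 (0.65), Vdr (-0.31), Apcdd1 (0.29) and Polk (0.20) with gene-end peaks only, and Fosl1 (0.49) and Polr2a (0.28) with chromosome medians removed. Sox10 (0.60) and Spdef (0.69) were smaller with gene-end peaks only, and Actb (0.30) with peaks in the gene body or within 50 kb. Larger values came with gene-end peaks only at Tek (1.38, and 1.28 within 10 kb), Dpp4 (-3.31), Krt13 (3.55) and Mmp7 (2.65). Hnf4g (-0.22) did not pass the test within 10 kb.

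**Figure D1:**
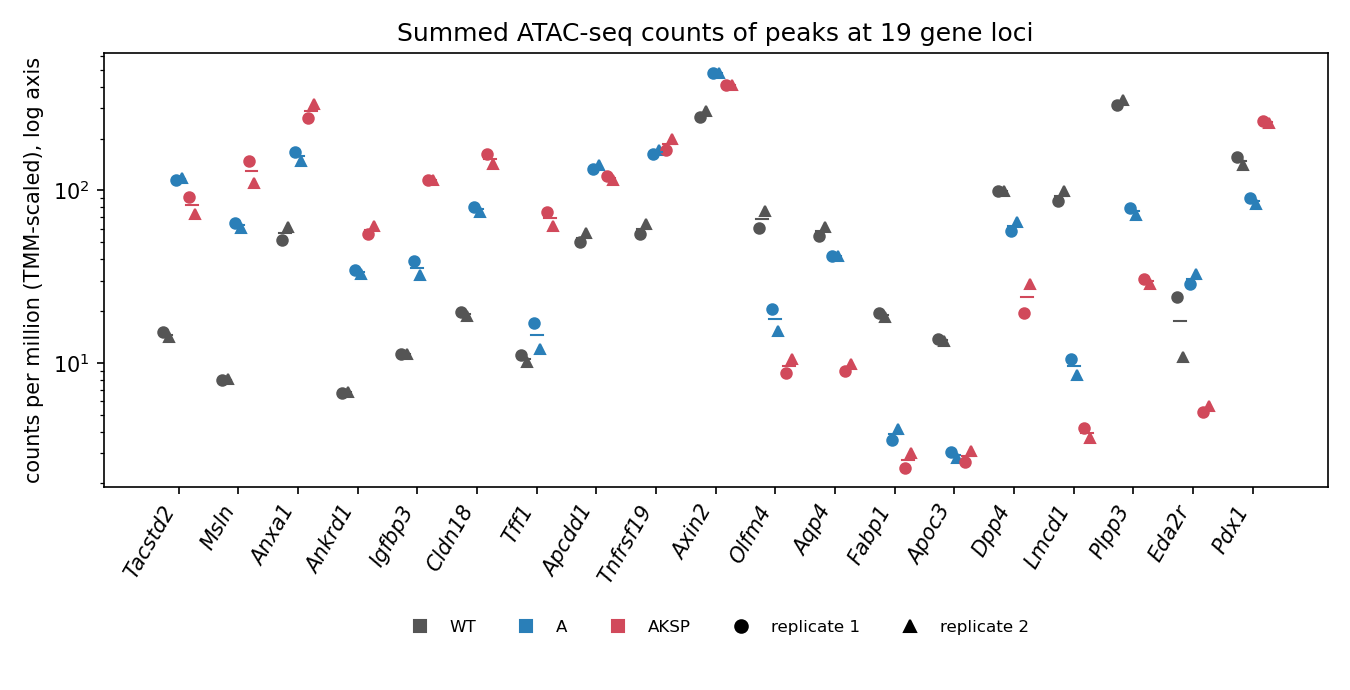
Summed counts of the peaks at 19 gene loci in CPM (log axis), with 1 symbol per library and a line at each group's mean; symbol shapes mark the replicate number. Tacstd2, Msln and Cldn18 are higher in both tumoroid groups than in WT, while Fabp1 falls from 18.9 to 3.85 and 2.74 CPM and Eda2r is lowest in AKSP.

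The comparison of AKSP with A asked what accompanies the Kras, Smad4 and Trp53 alleles beyond loss of Apc. The labels do not give the origin of the cultures, so the alleles cannot be told apart from other differences between them. Y-gene peaks (2.84-fold higher in A) and whole chromosomes also differed, as set out under Other observations. Between AKSP and A, 13 of 22 fetal and regenerative markers rose, a limma camera call that did not hold with an estimated correlation (adjusted p = 0.899). Tacstd2, in contrast, fell by 0.51 on the log2 scale, from 117 ± 2.5 CPM in A to 82.0 ± 13 in AKSP, and was named here after its values were seen. It lies on chromosome 6, whose median was -0.20 in AKSP vs A. With chromosome medians removed, Tacstd2 was at -0.32 in AKSP vs A and still passed the test. Of the p53 targets, 11 of 23 fell, without a call of the list by limma camera (adjusted p = 0.130, or 0.00661 and called with gene-end peaks only). Igfbp3 rose 3.20-fold, from 35.7 ± 4.6 CPM in A to 115 ± 0.69 in AKSP (SD, n = 2). Tff1 rose 4.69-fold, from 14.5 ± 3.5 to 69.0 ± 9.1 CPM. Eda2r (chromosome X, 97333837 to 97377234), a receptor gene and p53 target, fell to 0.177 of A, from 30.7 ± 2.7 to 5.42 ± 0.29 CPM.

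In this comparison, 3520 loci were higher and 3408 lower in AKSP, and 19422 peaks were higher and 20815 lower, or 24.1% of those tested. With library sizes alone as scaling, the share of called loci that were higher moved from 50.8% to 36.0%. The largest rises were at 1700037H04Rik (2.79 ± 0.20 log2, SE), the zinc finger gene Zic5 (1.97 ± 0.16), the glycine decarboxylase gene Gldc (1.97 ± 0.09), the calcium channel gene Cacnb2 (1.84 ± 0.11), Ly6e (1.79 ± 0.20, but 1.12 within 10 kb and 0.97 with gene-end peaks only) and Igfbp3. The largest falls were at LOC115488350 (-2.49 ± 0.10), Lmo3 (-2.37 ± 0.10), Gm32280 (-2.31 ± 0.12), the phosphodiesterase gene Pde3a (-2.23 ± 0.08), Gm826 (-2.15 ± 0.20) and the water channel gene Aqp4 (-2.15 ± 0.10). The edgeR adjusted p of the 12 loci lay between 4.44e-08 and 3.11e-05.

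Fetal and regenerative markers rose at 13 of 22 loci and fell at 2 (15 and 2 adjusted over the list alone; limma camera adjusted p = 0.00464; adjusted p = 0.899 with an estimated correlation). The call of the list was also lost with gene-end peaks only (limma camera adjusted p = 0.0627). Il33 rose by 0.84 ± 0.09, Msln by 1.05 ± 0.12 and Anxa1 by 0.87 ± 0.10. Il33 and Anxa1 lie on chromosome 19, where the median of all peaks was 0.39, and their values with chromosome medians removed were 0.44 and 0.47. In the planned test no other list was called. YAP/TEAD targets rose at 9 of 23 and fell at 4 (limma camera adjusted p = 0.130), with Myof at 0.99 ± 0.07 (0.58 with chromosome medians removed) and Asap1 at 0.85 ± 0.09.

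Targets of p53 fell at 11 of 23 loci and rose at 2 (13 and 4 adjusted over the list alone), and camera gave no call (limma, adjusted p = 0.130), but it called the list with gene-end peaks only (0.00661) and without A replicate 1 (0.0475). Besides Eda2r, Phlda3 fell by 0.61 and Bbc3, the gene of the cell death protein Puma, by 0.42 on the log2 scale. MAPK and AP-1 targets rose at 10 of 23 and fell at 2 (0.130), including the ERK phosphatase genes Dusp5 (0.71 ± 0.07, on chromosome 19, and 0.30 with chromosome medians removed) and Dusp6 (0.55 ± 0.07), and Ier3 (0.81 ± 0.08). Gastric and squamous markers rose at 7 of 18 and fell at 1 (0.130), with Cldn18 at 0.97 ± 0.09 and Krt13 at 1.12 ± 0.12. With peaks within 10 kb, camera called this list (limma, adjusted p = 0.0293). The YAP/TEAD, MAPK and AP-1, and gastric and squamous counts were the same adjusted over the list alone.

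Wnt targets fell at 8 of 25 and rose at 5 (limma camera adjusted p = 0.675; 9 and 6 adjusted over the list alone), with Sox4 down by 0.84, Nkd1 by 1.20 and Lef1 by 1.37. Stem cell markers fell at 7 of 18 and rose at 2 (0.513), with Rgmb at -0.46 ± 0.07 and Prom1 at 0.59 ± 0.07. Enterocyte markers fell at 9 of 25 and rose at 4 (0.278, or 0.0236 without AKSP replicate 2; 10 and 4 adjusted over the list alone), with Cyp3a11 and Dpp4 lower (-2.05 ± 0.16 and -1.37 ± 0.14) and the alkaline phosphatase gene Alpi higher (1.14 ± 0.13). TGF-beta and BMP targets rose at 7 of 19 and fell at 6 (0.830), with Serpine1 at 1.02 ± 0.11, Tgfbi at -1.14 ± 0.12 and Msx1 at -0.89 ± 0.10. Goblet markers rose at 4 of 14 and fell at 6 (0.768), with Muc2 at 1.36 ± 0.15, Fcgbp at -0.44 ± 0.08 and Klk1 at -0.87 ± 0.18. Paneth markers fell at 2 of 7 (0.212), namely Mptx1 (-1.82 ± 0.21) and Lyz1 (-1.66 ± 0.23). Pdx1 rose by 1.52 ± 0.08. The stem cell, TGF-beta and BMP, goblet and Paneth counts were the same adjusted over the list alone. The TGF-beta and BMP median was 0.10 and its mean -0.03, and the goblet median was -0.04 and its mean 0.03.

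The other lists gave no call between AKSP and A. Enteroendocrine markers rose at 1 of 22 and fell at 9 (limma camera adjusted p = 0.513; 2 and 9 adjusted over the list alone), and tuft markers fell at 5 of 22 and rose at none (0.234). Identity factors rose at 5 of 20 and fell at 6 (0.790; 6 and 7 adjusted over the list alone). EMT and matrix genes rose at 4 of 18 and fell at 5 (0.939; 8 and 6), with a median of 0.02 and a mean of -0.13. Stromal, immune and endothelial markers rose at 1 of 22 and fell at 4 (0.488; 0 and 2). Colon and posterior gut markers fell at 2 of 10 (0.617), and proximal markers rose at 1 of 7 and fell at 2 (0.948), with a median of -0.21 and a mean of 0.06. Housekeeping loci rose at 2 of 13 and fell at 1 (0.513). The tuft, colon, proximal and housekeeping counts were the same adjusted over the list alone.

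The peaks with the largest rises lay near Zic5 (chromosome 14, 122434555 to 122435000, log2 fold change 4.52 ± 0.55) and outside protein-coding genes on chromosome 17 (62054774 to 62055223, 4.30 ± 0.37) and chromosome 16 (62554249 to 62554933, 4.27 ± 0.28). At the Zic5 peak the WT libraries differed, at 0.154 and 2.41 CPM, against means of 0.252 in A and 5.72 in AKSP. The Calr4 peak was at least 117-fold lower. Peaks inside Cobl (chromosome 11, 12374875 to 12375445) and Aim2 (chromosome 1, 173420280 to 173420753) had log2 fold changes of -4.67 ± 0.69 and -4.47 ± 0.65. The WT libraries differed at both, with 26.5 and 1.02 CPM at the Cobl peak and 8.01 and 0.512 CPM at the Aim2 peak. WT replicate 2 lay near the AKSP means (1.05 and 0.270 CPM), and WT replicate 1 nearer the A means (27.4 and 5.77 CPM). Low counts at these peaks thus also occurred without the added alleles. With gene-end peaks only, Gldc (0.21), Muc2 (-0.47), Il33 (0.02) and Dusp6 (-0.18) did not pass the test, and Dusp6 was also lost with peaks within 10 kb (-0.08). Past the test but smaller were Gldc (0.69) and Muc2 (0.76) within 10 kb, Fcgbp (-0.29) and Prom1 (0.34) with gene-end peaks only, and Bbc3 (-0.24) and Fcgbp (-0.26) with chromosome medians removed. Gm32280 (-4.15), Krt13 (2.32) and Nkd1 (-1.82) were larger with gene-end peaks only. Without A replicate 1, peaks called higher fell to 10559.

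**Figure D2:**
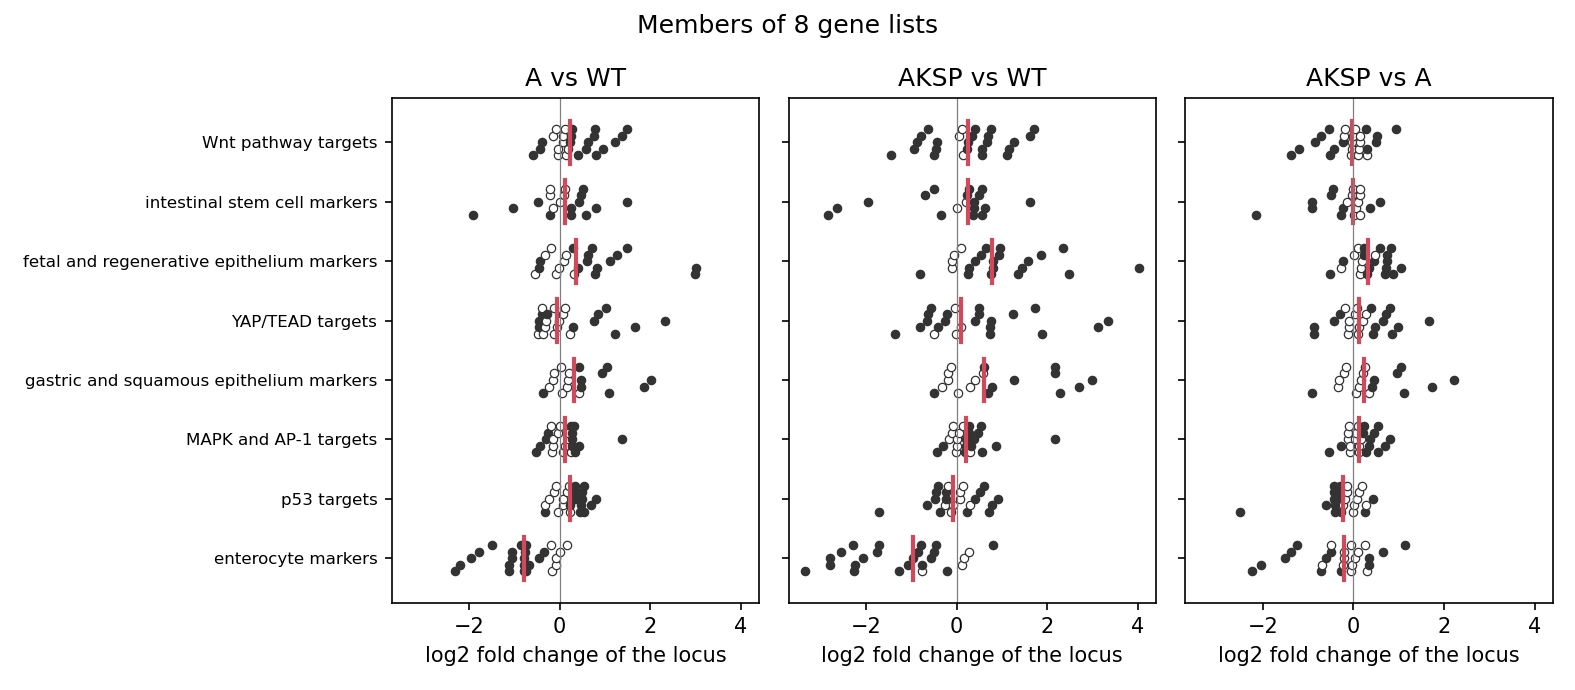
Log2 fold change of each member of 8 gene lists in the 3 comparisons; filled points passed the edgeR test at adjusted p under 0.05, open points did not, vertical spread within a list is for display, and red bars are list medians. The enterocyte median is -0.78 in A vs WT and -0.96 in AKSP vs WT, and the fetal and regenerative median is 0.36, 0.78 and 0.32 in the 3 comparisons.

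Of the peaks higher in A than in WT, 22366 (80.2%) were also higher in AKSP than in WT, and of those lower in A, 25122 (86.2%) were also lower. Independent lists of these sizes would share 6923 and 7438. Only 528 peaks were called in opposite directions. The covariance of the log2 differences was 1.10, against 0.0599 in 10 simulations of unchanged groups with the same WT libraries, and the correlation was 0.846 against 0.557. Both comparisons use the same 2 WT libraries, too few to give each comparison 2 of its own. The simulations include the spread between these libraries, but no trait that sets both apart from the tumoroids, such as sex. Part of the excess may therefore still come from the shared controls.

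Called peaks lay away from gene ends more often than uncalled ones. In A vs WT, 6.19% of higher and 12.4% of lower peaks were gene-end peaks, against 15.2% of uncalled peaks (odds ratios 0.369 and 0.791, two-sided Fisher exact test). For AKSP vs WT the shares were 8.72% and 12.5% against 15.8% (0.510 and 0.763), and for AKSP vs A 8.24% and 9.34% against 14.6% (0.526 and 0.604). Peaks are not independent replicates, and peak abundance was not held constant in this comparison.

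Whole chromosomes differed in AKSP. In AKSP vs WT the median log2 fold change was 0.43 over the peaks of chromosome 19 and 0.34 over those of chromosome 15, and -0.21 and -0.20 over chromosomes 10 and 6. The SD of the 19 autosome medians was 0.20 in AKSP vs WT and 0.176 in AKSP vs A, against 0.0420 in A vs WT. Chromosome 6 stood at -0.11 in AKSP replicate 1 and -0.29 in AKSP replicate 2 relative to the WT mean. With chromosome medians removed, 5542 loci were called between AKSP and A, and 65.0% of the 6928 called before kept their call and direction.

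**Figure D3:**
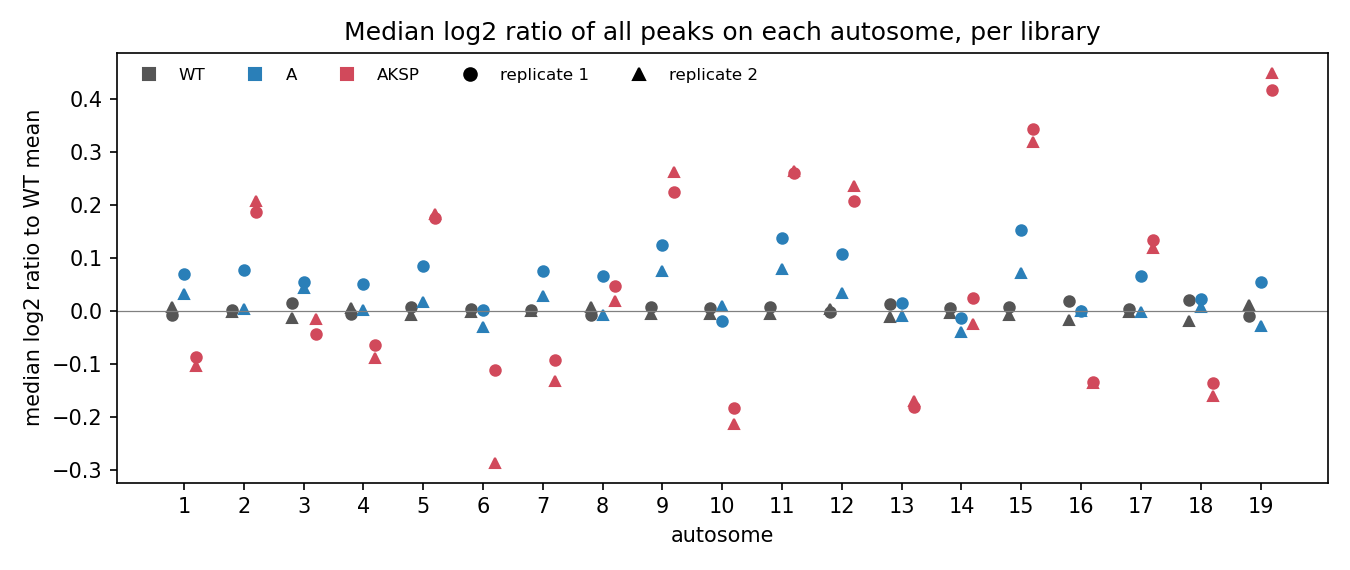
Median log2 ratio to the WT mean over all peaks of each of the 19 autosomes, with 1 symbol per library; colours mark the groups and symbol shapes the replicate number. AKSP libraries depart from WT by up to 0.43 on chromosome 19 as a group, and chromosome 6 differs between the AKSP replicates (-0.11 and -0.29).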

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

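Each locus here was picked out by values already seen. Opposite directions against WT and a called difference between AKSP and A defined it. The test of AKSP against A was planned, but its call was a condition here and adds no support.

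The search covered loci named in the report that passed the test in opposite directions in A and in AKSP against WT. They also had to be called between AKSP and A, and 6 were found. Pdx1 was lower in A (log2 fold change -0.77 ± 0.08 SE) and higher in AKSP (0.75 ± 0.08), and the difference between AKSP and A was 1.52 ± 0.08. Zic5 went from -0.96 ± 0.16 to 1.01 ± 0.16 (difference 1.97), Dusp5 from -0.52 ± 0.07 to 0.19 ± 0.07 (0.71) and Prom1 from -0.21 ± 0.07 to 0.39 ± 0.07 (0.59). Eda2r was higher in A (0.80 ± 0.26) and lower in AKSP (-1.70 ± 0.27), with a difference of -2.50, and Nkd1 went from 0.41 ± 0.11 to -0.79 ± 0.11 (-1.20). The edgeR adjusted p of these 6 differences, which had to be under 0.05, lay between 2.58e-07 and 4.78e-05.

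Over all loci, 146 met these conditions, of which 91 were lower in A and higher in AKSP and 55 the other way. The WT libraries differed at Eda2r, with a mean of 17.5 ± 9.4 CPM. They also differed at a peak counted in the Zic5 locus, at 0.154 and 2.41 CPM. With chromosome medians removed, 80 of the 146 still met the conditions. Dusp5, on chromosome 19, no longer did, as it was lower in both A (-0.50) and AKSP (-0.20), with a difference of 0.30. The other 5 named loci kept both directions. No other test of these opposite directions was made.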

How the results depend on the processing

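Alternatives added after the data were seen were the authors' size factors, a mean CPM of at least 2, thinning to equal depth, peaks in the gene body or within 50 kb, and removal of chromosome medians for loci and lists. For the gene body setting, each peak went only to the gene with the nearest body. The GC offsets, the replicate block with GC offsets and both alternatives of the motif test were not run for want of a genome.

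Over the loci named by the rule, 3241 values under an alternative stayed on their side of the threshold without a called change of direction, 74 lost the call, 5 gained it and 15 changed sign. Of these 15, 11 also lost the call, so 85 values lost it in all. Itln1 passed the test in the other direction, and 3 Trp53 values, uncalled before, gained a call. Some uncalled values among the 3241, at Apc and Trp53, changed sign. Assignment of peaks accounted for most, with 27 losses without and 11 values with another sign under gene-end peaks only, and 17 and 2 within 10 kb. With gene-end peaks only, the log2 values with another sign in A vs WT were 0.0454 at Acta2, 0.41 at Creb3l3, -0.65 at Itln1, 0.0457 at Kras and -0.31 at Spef2. They were -0.53 at Muc2 and 1.26 at Trp53 in AKSP vs WT, and -0.18 at Dusp6, -0.12 at Gip, -0.47 at Muc2 and 0.0471 at Plcg2 in AKSP vs A. Within 10 kb, Bcas1 changed sign in A vs WT (0.0860) and Dusp6 in AKSP vs A (-0.0843), both without a call. Trp53 in AKSP vs WT changed sign without WT replicate 2 (0.83; -0.74 without WT replicate 1) and with peaks in the gene body or within 50 kb (0.50). Apart from the left-out library, these settings use fewer or other peaks, and the cause at each locus was not tested.

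Against a fold of 1.5, 15565 peaks were higher and 15063 lower in A vs WT, and 7633 and 8617 in AKSP vs A, as a stricter test must give fewer. With a mean CPM of at least 2, fewer peaks entered, and the counts were 16310 and 15396 for A vs WT, 20976 and 21577 for AKSP vs WT, and 12638 and 13450 for AKSP vs A. With gene-end peaks only, 2447 loci were higher in A vs WT, and 2158 higher and 2202 lower in AKSP vs A. With library sizes alone, the median of all peaks in A vs WT moved from 0.04 to 0.14, which by itself turned the chromosome 10 median A vs WT from -0.00301 to 0.0927 and the chromosome 6 median A vs WT from -0.00959 to 0.0897. With the same scaling, 36.0% of called loci in AKSP vs A were higher, against 50.8%. The DESeq2 test kept 83.0%, 87.6% and 79.5% of the called peaks of A vs WT, AKSP vs WT and AKSP vs A.

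Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the others, gave 18725 to 28599 higher and 19187 to 30700 lower peaks in A vs WT. In AKSP vs A it gave 10559 to 20081 higher and 13434 to 21639 lower peaks, with the lowest counts without A replicate 1 and A replicate 2. Loci higher in A vs WT ranged from 2069 (without WT replicate 2) to 4063, with 2346 without WT replicate 1. Called lists in AKSP vs A ranged from 1 to 3.

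The lists called numbered 5 in A vs WT, 3 in AKSP vs WT and 1 in AKSP vs A. With an estimated correlation the counts were 0, 0 and 0, since the estimates for called lists, 0.129 to 0.317, exceed the preset 0.01, and with fry, which asks another question, 9, 13 and 4. Within 10 kb, 2 lists were called in AKSP vs A, the added one being the gastric and squamous list (limma camera adjusted p = 0.0293). That list was also called there without A replicate 1 (0.0120) and without AKSP replicate 2 (0.0382), where the enterocyte list was called too (0.0236). In A vs WT it was lost with gene-end peaks only (0.116). The p53 list of AKSP vs A was called with gene-end peaks only (0.00661) and without A replicate 1 (0.0475), and the fetal list was lost with gene-end peaks only (0.0627).

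Deviations from group means of same-numbered libraries correlated at 0.007 (WT and A), -0.009 (WT and AKSP) and 0.119 (A and AKSP), so the numbers were not taken as pairs. With the replicate number as a block, 28935 peaks were higher and 30316 lower in A vs WT, 42218 and 43437 in AKSP vs WT, and 20809 and 22247 in AKSP vs A. The block fit kept 99.4% to 99.8% of the called peaks and loci.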

Other observations

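The patterns below were noticed in the data. Chosen only after the result was seen were the window test on chromosome 6 and the test on the deeper AKSP library. The test on X genes was devised after the Xist and Y values were known.

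Autosome medians in AKSP vs A ranged from -0.21 on chromosome 10 to 0.39 on chromosome 19. A trend with gene density, a stand-in for GC content, is argued against by an SD of autosome medians of 0.176 after its removal, against 0.180 before, and a trend with peak abundance by 0.176 with abundance-trended offsets. Medians of the least and the most abundant peaks (3 equal classes) correlated at 0.985 across the 19 autosomes, so copy number of whole chromosomes in part of the AKSP cells is a candidate explanation, as is any other cause that shifts all peaks of a chromosome. Between the AKSP libraries, chromosome 6 stood out at -0.17 (the next lowest autosome was at -0.04), and -0.17 was left after removal of the gene density trend, which argues against that trend; all 15 windows of 10 Mb lay below the genome median, as any shift of the whole chromosome would give, so its cause stays open. GC content itself and a biological change of whole chromosomes other than copy number stay open, as neither could be tested.

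Peaks of low abundance were higher in the tumoroids, with a median log2 fold change of 0.42 in A vs WT and 0.49 in AKSP vs WT over the lowest 10% of peaks. Lower signal over background in the tumoroids would lower their share of counts in the strongest gene-end peaks, but the lowest WT share minus the highest tumoroid share was -2.08 percentage points. After thinning to equal depth the median in A vs WT was 0.39. Thinning keeps the expected ratio at each peak and the same list of peaks, so it cannot decide on unequal depth. Peaks called mainly in the deepest library remain open for A, since A replicate 1 exceeded A replicate 2 by 0.27 there. For AKSP the like difference was 0.01, which bears only on peaks called in the deeper AKSP library. It cannot decide on peaks called in pooled libraries or in A, which could be higher in both AKSP libraries alike. A biological gain of weak sites by genotype was not tested and stays open.

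The Xist peak at 103481199 to 103482305 on chromosome X had 9.45 ± 0.15 CPM in WT, 0.387 ± 0.25 in A and 0.476 ± 0.012 in AKSP. The Xist peak at 103477245 to 103477959 differed less, with 8.93 CPM in WT, 2.93 in A and 2.54 in AKSP. A weaker one at 103483141 to 103483440 had 1.53, 0.0378 and 0.106 CPM. Over 6 peaks of 4 Y genes, WT reached 0.358% and AKSP 35.2% of the level in A. Gene-end peaks of Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, lay below the median of X peaks by a median of -0.23 in A vs WT and -0.32 in AKSP vs WT, narrowly past the bound of 0.2 in A. The 4 Y genes held almost no counts in WT and clear counts in both tumoroid groups. Sex-linked signal therefore differed along with genotype in both comparisons with WT. WT organoids from female animals and tumoroids from male animals would give such values, and sex was not checked in any other way. The 2.84-fold higher Y level in A than in AKSP was not explained by any test.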
